A study of Arabidopsis thaliana with 12 samples.

How the data were processed

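Per the labels' protocols, RNA of the leaves was taken with Trizol and cleaned on a column, and libraries were made after poly(A) selection. Per the submitters' processing notes, reads were checked with FastQC 0.11.7, aligned with STAR 2.4.0.1 to TAIR10 and normalised with DESeq2 1.20.0. The counting tool, the strand of the libraries, the annotation release and any filter are not given. The deposited signal values are read counts divided by 1 size factor per library, made by the authors with DESeq2. Dividing each library by its smallest step gave whole numbers for 100% of non-zero values (within 0.001), so reads were recovered per library, and the size factors implied equal recomputed medians of ratios. Size factors lay between 1.171 and 1.269 in control, 1.129 and 1.308 in high light, 1.048 and 1.527 in heat and 0.5353 and 0.6048 in the combination.

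The file lists 32833 loci, 32548 of them in the reference gene table of TAIR10.1, used for names only. Genes with a mean normalised count of at least 10 were tested, 19309 in all. Values were taken as log2(normalised count + 1), and limma 3.58.1 (limma-trend, R 4.3.3) was fitted to all 12 libraries at once with 1 mean per group. The 6 comparisons were each stress against control, the combination against each single stress, and the interaction. P-values were adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05, and tests are two-sided. Genes apart in the combination had to pass against each of the other 3 groups with the same sign.

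The groups, comparisons, tests, gene lists, naming rule and all alternatives but those named below as later were chosen before the data were examined. The 24 lists (392 members) covered heat shock proteins, heat shock factors, endoplasmic reticulum chaperones, jasmonate synthesis and signalling, abscisic acid, salicylic acid, antenna proteins, photosystem subunits, photosystem II repair, early light-induced proteins, the Calvin cycle, flavonoids, oxygen scavenging, zinc finger regulators, the clock, starch and raffinose, the cell cycle, senescence, and markers of guard cells, phloem, epidermis, xylem and flowers. Of these members 380 matched a symbol in the reference and 12 did not and were left out. For CNX2 and MET1 the symbol belongs to a locus other than that listed, and was used. Lists were tested with camera (correlation preset at 0.01), adjusted over 138 tests, of which 49 passed and 0 did so with an estimated correlation (lowest adjusted p = 0.609). The self-contained test fry, which asks whether the members move on balance in 1 direction, passed 66, with 48 of the 49 in the same direction.

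The naming rule took the 5 largest rises and falls per comparison among genes past the threshold with a symbol and a mean of at least 50 in the higher group, without overlap of the libraries (not required for the interaction). It added the 3 members with the largest change from each called list, 1 from each other list with a changed member, and 15 genes given always. For the combination against each single stress it took the first and last of these parts. For genes apart it took 5 per direction by the smallest of 3 changes. MYC2, among the 15, is listed at 0 in 11 of 12 libraries and at 0.954 in heat library 3 and was not tested.

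Alternatives were pseudocounts of 0.5 and 10, no filter and a filter at 50, TMM and upper-quartile scaling, a robust variance estimate, fits of only the compared groups, the replicate number as a block, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, an adjusted p under 0.01, an absolute log2 change of at least 1, and each library left out in turn. Chosen after seeing the data were all listed loci, nuclear genes alone, heat library 1 and combination library 2 both left out, the lists without CNX2 and MET1, and library totals as the scaling. Against the deposited scaling, TMM moved the median of all genes by -0.12 in the combination against control and against high light and by -0.11 in the combination against heat and in the interaction. Upper-quartile scaling moved it by -0.11 in heat, -0.19 in the combination and -0.17 in the combination against high light.

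Simulated data held 200 changed genes per comparison, far fewer than called here, so recovery does not carry over. The test found 89.4% of 4-fold, 25.4% of 2-fold and 4.48% of 1.5-fold changes in high light, and 59.1%, 7.46% and 0% in the interaction. False calls were 3.66% of calls in high light and 7.87% to 11% in the 5 others. The floor for a group at 0 was 3 counts per library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.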

Results

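The data are leaf transcriptomes of Arabidopsis thaliana, the thale cress, in the wild-type accession Col-0. Plants aged 30 days had grown at 23 °C with 12 h of light per day at 50 µmol m-2 s-1. They were left untreated (control), moved to 600 µmol m-2 s-1 (high light), moved to 42 °C (heat) or given both together (high light and heat, called the combination below) for 7 h, with 3 libraries per group and 12 in all. The design asks what each stress does to the leaf transcriptome and whether the response to the combination can be read from those to the single stresses. Recovered reads per library numbered 32799975 to 34206515 in control and 33626361 to 36768410 in high light, 34688170 to 36938786 in heat and 29814116 to 32892194 in the combination. Levels are normalised read counts given as mean ± SD (n = 3 per group), and changes are log2 differences ± SE of log2(normalised count + 1), which understate the change of genes with few reads. The labels do not say that the 3 libraries of a group came from separate plants, so the p-values measure the spread between these libraries, which may be technical.

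Transcripts of the 20 tested heat shock protein genes took 0.027% ± 0.00375 of the reads in control, 0.0725% ± 0.0203 in high light, 3.03% ± 2.49 in heat and 11.7% ± 3.33 in the combination (SD, n = 3 each). The 3 heat libraries differed in this share, at 0.783%, 2.6% and 5.71%. Transcripts of the mitochondrial genome took 0.00827% ± 0.00457 of reads in control, 0.00629% ± 0.000351 in high light, 0.102% ± 0.0233 in heat and 0.0939% ± 0.0315 in the combination. Chloroplast genome transcripts took 0.0279% ± 0.00495, 0.0253% ± 0.00734, 0.0536% ± 0.00492 and 0.0939% ± 0.103 in the same order, with 0.212% in combination library 2 against 0.0422% and 0.0274% in the other libraries of that group. Across the 19309 genes tested, libraries of a group correlated at Pearson's r = 0.986 to 0.99 in control, 0.984 to 0.986 in high light, 0.936 to 0.973 in heat and 0.955 to 0.975 in the combination. These correlations are across genes, which are not independent replicates.

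**Figure D1:**
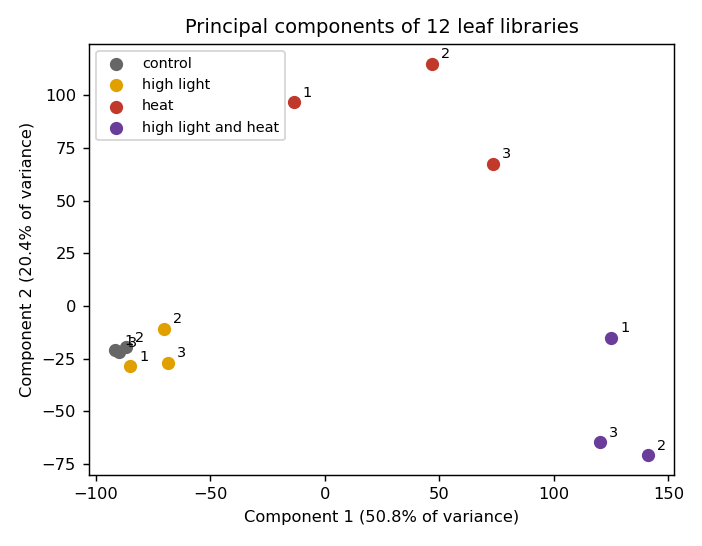
Principal components 1 and 2 (50.8% and 20.4% of the variance; arbitrary units) of log2(normalised count + 1) over 19309 genes. Each point is 1 library with its replicate number and the colour gives the group; the 3 heat libraries spread along component 1 from -13.7 to 73.2.

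High light alone raised ELIP1, ELIP2 and most genes of flavonoid synthesis and lowered most antenna and photosystem genes. ELIP1 (AT3G22840), which codes for an early light-induced chlorophyll-binding protein, was at 50.2 ± 30.4 in control and 57460 ± 21500 in high light, a rise of 10.3 ± 1.12 (adjusted p = 2.25e-05). Its relative ELIP2 (AT4G14690) rose by 10.25 ± 1.07 (adjusted p = 1.7e-05), and CHS (AT5G13930), the chalcone synthase that opens flavonoid synthesis, rose from 727 ± 193 to 149700 ± 48100, by 7.66 ± 0.36 (adjusted p = 2.96e-07). LHCB1.1 (AT1G29920), an antenna protein gene of photosystem II, fell from 156600 ± 8100 to 14500 ± 4330, a change of -3.48 ± 0.38 (adjusted p = 2.53e-05). Of 19309 genes, 3496 were higher and 3205 lower than in control (limma, Benjamini-Hochberg adjusted p under 0.05). ELIP1 was 9.66 without control 1. ELIP2 was 11.04 without high light 2.

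Among flavonoid and anthocyanin synthesis genes, 22 of 24 were higher and 0 lower (23 and 0 adjusted over the list alone), median 5.69, camera adjusted p = 2.53e-18 (adjusted p = 0.609, estimated correlation). The regulator PAP2 (AT1G66390) rose by 8.38 ± 0.8, TT7 (AT5G07990), the flavonoid 3'-hydroxylase, by 8.17 ± 0.49 and UGT78D3 (AT5G17030), a flavonol glycosyltransferase outside the list, by 9.3 ± 0.57. Without high light 2 the change of TT7 was 8.8. Among light-harvesting antenna proteins, 2 of 20 were higher and 16 lower (2 and 16 adjusted over the list alone), median -2.52, camera adjusted p = 2.54e-08 (adjusted p = 0.609, estimated correlation). LHCB1.4 (AT2G34430) changed by -8.24 ± 0.5, LHCB2.3 (AT3G27690) by -5 ± 0.78 and LHCB4.2 (AT3G08940) by -3.94 ± 0.31. Members of the LHCB1 and LHCB2 families are near-identical, and reads may have been split among them, so their single values are uncertain. Among nuclear-encoded photosystem subunits, 2 of 24 were higher and 21 lower (2 and 22 adjusted over the list alone), median -1.49, camera adjusted p = 1.37e-08 (adjusted p = 0.633, estimated correlation). PSAD2 (AT1G03130) was at -2.73 ± 0.34, PSBQ2 (AT4G05180) at -2.49 ± 0.2 and PSAO (AT1G08380) at -2.39 ± 0.25.

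Among Calvin cycle genes, 8 of 19 were higher and 1 lower (10 and 1 adjusted over the list alone), median 0.56, camera adjusted p = 0.0162 (adjusted p = 0.701, estimated correlation). The small Rubisco subunits RBCS2B (AT5G38420) and RBCS1B (AT5G38430), close copies, rose by 1.67 ± 0.24 and 1.64 ± 0.24, and the aldolase FBA1 (AT2G21330) by 1.63 ± 0.27. Without control 2 the list was no longer called (camera adjusted p = 0.0561). Among reactive oxygen scavenging enzymes, 12 of 27 were higher and 3 lower (15 and 3 adjusted over the list alone), median 0.56, camera adjusted p = 0.00922 (adjusted p = 0.633, estimated correlation). The stromal ascorbate peroxidase SAPX (AT4G08390) rose by 3.04 ± 0.22, the catalase CAT2 (AT4G35090) by 2.33 ± 0.52 and the cytosolic ascorbate peroxidase APX1 (AT1G07890) by 2.3 ± 0.22. Among salicylic acid genes, 1 of 12 were higher and 6 lower (1 and 7 adjusted over the list alone), median -1.29, camera adjusted p = 0.0113 (adjusted p = 0.609, estimated correlation). The transcriptional regulators SARD1 (AT1G73805), WRKY70 (AT3G56400) and CBP60G (AT5G26920) changed by -2.68 ± 0.54, -2.62 ± 0.33 and -2.45 ± 0.57.

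The largest falls besides LHCB1.4 were PORA (AT5G54190), a protochlorophyllide oxidoreductase of chlorophyll synthesis, at -8.44 ± 0.7, the expansin EXPA8 (AT2G40610) at -7.18 ± 0.7, PGL1 (AT1G13700), a phosphogluconolactonase, at -6.93 ± 0.44 and the senescence-associated SEN1 (AT4G35770) at -6.71 ± 0.44. VSP1 (AT5G24780), a vegetative storage protein gene induced by jasmonate, rose by 5.08 ± 1.09, CYP707A2 (AT2G29090), an abscisic acid hydroxylase, by 3.71 ± 0.42, the photosystem II protease FTSH8 (AT1G06430) by 2.49 ± 0.33, the coactivator MBF1C (AT3G24500) by 3.37 ± 0.71 and the zinc finger gene ZAT12 (AT5G59820) by 3.42 ± 0.62. GOLS2 (AT1G56600), a galactinol synthase, changed by -3.48 ± 0.34 and AOC1 (AT3G25760), an allene oxide cyclase of jasmonate synthesis, by -1.32 ± 0.19. HSFA2 (AT2G26150), a heat shock factor, rose by 5.13 ± 1.51 (adjusted p = 0.0188) with 2077 ± 2370 in high light, and this call ended without control 1 or 3 or high light 2 or 3 (3.97 to 4.85, adjusted p = 0.0599 to 0.0893). HSFA2 was 5.75 without control 2 and 6.56 without high light 1. EXPA8 was -6.55 without high light 1 and -8 without high light 2. VSP1 lay between 4.09 and 5.99 without control 2 or 3 or high light 2. ZAT12 was 4.02 without high light 2.

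Close to the threshold were ERDJ3A (AT3G08970) at 1.47, PRR5 (AT5G24470) at -1.15, KAT1 (AT5G46240) at 0.61, SULTR2;1 (AT5G10180) at -0.69 and CER5 (AT1G51500) at -0.54, with adjusted p from 0.0281 to 0.0452. The ERDJ3A call ended without control 1, 2 or 3 or high light 2 or 3 (1.14 to 1.57, adjusted p = 0.0762 to 0.168), and that of PRR5 without control 2 or 3 or high light 1 or 3 (-1.01 to -1.08, adjusted p = 0.0854 to 0.0978). The KAT1 call ended without control 1 or 2 or high light 1 or 3 (0.54 to 0.63, adjusted p = 0.0639 to 0.104), that of SULTR2;1 without control 2 or 3 or high light 1 or 3 (-0.5 to -0.77, adjusted p = 0.0662 to 0.186) and that of CER5 without control 1, 2 or 3 or high light 1, 2 or 3 (-0.5 to -0.59, adjusted p = 0.0616 to 0.124). With library totals the KAT1 and CER5 calls ended as well (0.0612 and 0.0596). The values of HSP101 (AT1G74310) (1.79 ± 1.28, adjusted p = 0.308), APX2 (AT3G09640) (1.08 ± 0.69, 0.252), LOX2 (AT3G45140) (0.5 ± 0.43, 0.411), AOS (AT5G42650) (0.21 ± 0.24, 0.539), JAZ10 (AT5G13220) (0.23 ± 0.58, 0.796), NCED3 (AT3G14440) (-0.89 ± 0.43, 0.134) and ZAT10 (AT1G27730) (1.23 ± 0.57, 0.114) did not pass, though ZAT10 did without control 2 (1.85). In the lists without a camera call (adjusted p 0.0874 to 0.972), the members higher and lower (in brackets those adjusted over the list alone, where different) were 5 and 0 of 20 heat shock proteins, 3 and 3 of 17 heat shock factors (4 and 4), 2 and 1 of 20 endoplasmic reticulum chaperones (0 and 1), 3 and 4 of 15 jasmonate synthesis genes, 6 and 3 of 20 jasmonate signalling genes, 4 and 4 of 24 abscisic acid genes, 3 and 8 of 21 photosystem II repair genes, 4 and 1 of 6 early light-induced genes and 4 and 1 of 7 stress zinc finger and NADPH oxidase genes. They were 0 and 2 of 19 clock genes (0 and 0), 4 and 3 of 12 starch and raffinose genes (5 and 3), 0 and 0 of 16 cell cycle genes, 1 and 4 of 8 senescence genes, 1 and 0 of 7 guard cell markers (0 and 0), 0 and 1 of 6 phloem markers (0 and 0), 0 and 1 of 6 epidermis markers (0 and 0) and 0 and 0 of 5 xylem markers, and the 1 flower marker tested, AG, did not pass. The heat shock protein list was called without control 2 (camera adjusted p = 0.0207) or high light 1 (0.00418), with no filter (0.0418) and with all listed loci (0.0434).

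**Figure D2:**
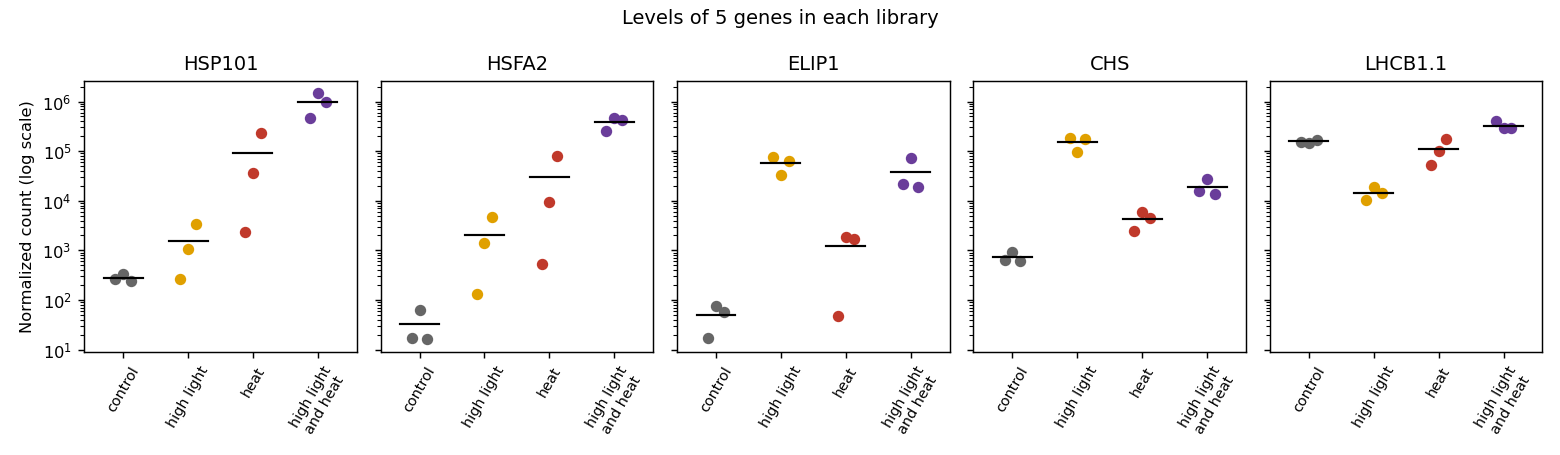
Normalised count (log axis) of HSP101, HSFA2, ELIP1, CHS and LHCB1.1 in each library, with group means as lines (n = 3 per group). HSP101 lies at 282 in control and 974000 in the combination on average and CHS is highest in high light at 149700.

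Heat alone raised every tested gene of the heat shock protein list and lowered most tested genes of the salicylic acid response and of cell division. HSP22.0 (AT4G10250), a small heat shock protein of the endoplasmic reticulum, was at 20.9 ± 32.5 in control and 110200 ± 70500 in heat, a rise of 13.41 ± 1.19 (adjusted p = 7.56e-06). The chloroplast HSP21 (AT4G27670) rose by 12.94 ± 1.07 (adjusted p = 5.18e-06) and the disaggregase HSP101 from 282 ± 47.1 to 90040 ± 123000, by 6.59 ± 1.28 (adjusted p = 0.00116). CYCB1;2 (AT5G06150), a mitotic cyclin gene, changed by -4.06 ± 0.68 (adjusted p = 0.000429), and PCC1 (AT3G22231), a pathogen-responsive gene, by -7.88 ± 0.53 (adjusted p = 1.82e-06). Of 19309 genes, 4745 were higher and 4783 lower than in control. HSP22.0 lay between 12.6 and 14.83 without control 1, 2 or 3 or heat 1. HSP21 lay between 12.1 and 13.89 without control 2 or 3 or heat 1. HSP101 was 8.36 without heat 1 and 5.04 without heat 3. CYCB1;2 was -4.88 without heat 1 and -3.12 without heat 2.

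Among heat shock proteins, 20 of 20 were higher and 0 lower (20 and 0 adjusted over the list alone), median 7.18, camera adjusted p = 2.45e-11 (adjusted p = 0.609, estimated correlation). The mitochondrial HSP23.6-MITO (AT4G25200) rose by 11.7 ± 1.24, HSP17.4 (AT3G46230) by 11.52 ± 1.27 and HSP18.2 (AT5G59720) by 11.37 ± 0.59. HSP23.6-MITO lay between 10.94 and 13.04, and HSP17.4 between 10.73 and 12.92 without control 1, 2 or 3 or heat 1 or 3. HSP18.2 was 11.96 without heat 1. Among heat shock factors, 11 of 17 were higher and 1 lower (11 and 1 adjusted over the list alone), median 1.5, camera adjusted p = 0.0113 (adjusted p = 0.609, estimated correlation). HSFA2 rose by 8.06 ± 1.51 and HSFA3 (AT5G03720) by 5.66 ± 0.67. HSFA2 lay between 6.34 and 9.96 without control 2 or heat 1 or 3. HSFA3 was 6.68 without heat 1. HSFA7B (AT3G63350) was at 0 in each control library and at 286 ± 346 in heat, at least 115-fold higher against a floor of 3 counts per library, which covers counting error only. Its heat libraries were at 0.7, 186.8 and 671.5. With HSFA7B at that bound the list's median was still 1.5.

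Among endoplasmic reticulum chaperones and unfolded protein response genes, 15 of 20 were higher and 2 lower (15 and 2 adjusted over the list alone), median 1.77, camera adjusted p = 0.000129 (adjusted p = 0.609, estimated correlation). The co-chaperone ERDJ3A rose by 5.19 ± 0.53, and the near-identical binding proteins BIP2 (AT5G42020) and BIP1 (AT5G28540) by 3.26 ± 0.35 and 2.52 ± 0.34. Among salicylic acid genes, 0 of 12 were higher and 8 lower (0 and 8 adjusted over the list alone), median -2.52, camera adjusted p = 0.000267 (adjusted p = 0.609, estimated correlation). SARD1 changed by -4.67 ± 0.54, WRKY70 by -3.95 ± 0.33 and the pathogenesis-related PR1 (AT2G14610) by -3.8 ± 1.36 (adjusted p = 0.0337). The PR1 call ended without control 1 or 2 or heat 2 or 3 (-2.64 to -4.11, adjusted p = 0.0582 to 0.151). PR1 was -5.23 without control 3 and -4.47 without heat 1.

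Among DNA replication and cell cycle genes, 0 of 16 were higher and 15 lower (0 and 15 adjusted over the list alone), median -1.63, camera adjusted p = 9.64e-06 (adjusted p = 0.609, estimated correlation). CDKB2;2 (AT1G20930), a mitotic kinase gene, changed by -2.47 ± 0.52 and the cyclin CYCA1;1 (AT1G44110) by -2.32 ± 0.63, and edgeR gave -1.56 (adjusted p = 0.0618) for the latter. CDKB2;2 was -3.16 without heat 1 and -1.76 without heat 3. CYCA1;1 was -3.33 without heat 1. Among nuclear-encoded photosystem subunits, 0 of 24 were higher and 11 lower (0 and 11 adjusted over the list alone), median -0.57, camera adjusted p = 0.00416 (adjusted p = 0.799, estimated correlation). PSAN (AT5G64040) was at -1.57 ± 0.26, PSAO at -1.27 ± 0.25 and PSB28 (AT4G28660) at -1.21 ± 0.28. LHCB2.3 changed by -2.27 ± 0.78 (adjusted p = 0.0284), a call that ended without control 1, 2 or 3 or heat 1 or 2 (-1.51 to -2.37, adjusted p = 0.0566 to 0.118) and in edgeR, at -1.21 (adjusted p = 0.226). Its value was -3.51 without heat 3.

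The largest falls besides PCC1 were LURP1 (AT2G14560), another pathogen-responsive gene, at -7.72 ± 0.6, the glucanase BG3 (AT3G57240) at -6.71 ± 0.74, the xylosyltransferase RGXT3 (AT1G56550) at -6.01 ± 0.69 and the phospholipase PLA2A (AT2G26560) at -5.58 ± 0.28. The largest change in the other lists was APX2 at 7.47 ± 0.69, the protease FTSH6 (AT5G15250) at 7.04 ± 0.49, the phosphatase HAI1 (AT5G59220) of abscisic acid signalling at 5.79 ± 0.73, GOLS1 (AT2G47180) at 5.15 ± 0.6, VSP2 (AT5G24770) at 3.99 ± 1.11, the AP2-type factor DREB2A (AT5G05410) at 3.57 ± 0.51, the clock gene CCA1 (AT2G46830) at 2.8 ± 0.69, NAP (AT1G69490) at 2.33 ± 0.45, XCP2 (AT1G20850) at 1.41 ± 0.26, FBA1 at 1.4 ± 0.27 and LOX3 (AT1G17420) at 0.93 ± 0.23. TT19 (AT5G17220), a flavonoid transport gene, changed by -2.82 ± 0.71. BG3 was -7.32 without heat 2. APX2 was 8.08 without control 3. HAI1 was 6.42 without control 1 and 5.05 without control 2. Without heat 1 and 3 in turn, GOLS1 was 5.88 and 4.41, DREB2A 4.25 and 2.95, CCA1 3.63 and 2.04, and TT19 -3.85 and -2.06. VSP2 lay between 3.21 and 4.95 without control 2 or 3 or heat 1 or 2. ELIP1 rose by 3.63 ± 1.12 (adjusted p = 0.0169) with 47.8, 1849 and 1709 in the 3 heat libraries, and this call ended without control 1 or heat 2 or 3 (2.74 to 3, adjusted p = 0.071 to 0.0849). ELIP1 was 5.36 without heat 1.

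CHS rose by 2.49 ± 0.36, APX1 by 1.73 ± 0.22, ZAT12 by 2.62 ± 0.62 and ZAT10 by 2.03 ± 0.57 (adjusted p = 0.0103). ZAT12 was 3.36 without heat 1, ZAT10 was 2.65 without control 2, and the ZAT10 call ended without control 3 (1.56, adjusted p = 0.0513). The guard cell gene MYB60 (AT1G08810) changed by -1.19 ± 0.37 (adjusted p = 0.0167) and the epidermal ATML1 (AT4G21750) by -0.67 ± 0.25 (adjusted p = 0.041). The MYB60 call ended without control 2 or 3 or heat 1 (-0.9 to -1.14, adjusted p = 0.053 to 0.0647), and that of ATML1 without control 1, 2 or 3 or heat 1, 2 or 3 (-0.62 to -0.71, adjusted p = 0.0548 to 0.109). ELIP2 (2.67 ± 1.07, adjusted p = 0.0536), LOX2 (-0.43 ± 0.43, 0.438), AOS (-0.35 ± 0.24, 0.236), JAZ10 (-0.32 ± 0.58, 0.669), NCED3 (0.66 ± 0.43, 0.225) and LHCB1.1 (-0.68 ± 0.38, 0.158) did not pass. Without heat 1, ELIP2 (4.14), LOX2 (-1.04) and AOS (-0.59) did, as did NCED3 (1.11) and LHCB1.1 (-1.1) without heat 3 and ELIP2 in edgeR (3.54). In the lists without a camera call (adjusted p 0.109 to 0.972), the members higher and lower (in brackets adjusted over the list alone) were 3 and 2 of 15 jasmonate synthesis genes (3 and 1), 7 and 2 of 20 jasmonate signalling genes (4 and 1), 6 and 3 of 24 abscisic acid genes, 0 and 4 of 20 antenna genes (0 and 2), 4 and 9 of 21 photosystem II repair genes, 2 and 1 of 6 early light-induced genes (3 and 1), 4 and 4 of 19 Calvin cycle genes, 5 and 5 of 24 flavonoid genes and 10 and 2 of 27 oxygen scavenging genes. They were 4 and 0 of 7 stress zinc finger and NADPH oxidase genes, 4 and 2 of 19 clock genes (2 and 2), 5 and 2 of 12 starch and raffinose genes (5 and 4), 1 and 1 of 8 senescence genes, 0 and 4 of 7 guard cell markers, 0 and 0 of 6 phloem markers, 0 and 1 of 6 epidermis markers (0 and 0) and 1 and 0 of 5 xylem markers, and AG did not pass. The antenna list was called without heat 2 (camera adjusted p = 0.0399) or heat 3 (0.0291), and the abscisic acid list with no filter (0.0459).

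All 39 tested mitochondrial genome genes were higher in heat (median 4.42) and the combination (4.33) than in control. ATMG00020 and ATMG01390 had the most reads of these in every library and weighed most in that genome's read share. In high light 4 of 39 were higher and 0 lower, with 7 higher without control 2 and 2 without control 3 or high light 1 or 3. Of 79 chloroplast genome genes, 17 were higher and 4 lower in heat (median 0.53), with 27 and 8 without combination 2 and 21 and 7 without combination 3. In the combination 29 were higher and 8 lower (median 0.84), against 18 and 12 without combination 2 (0.153), 32 and 5 without combination 1 (1.15), 34 and 5 without combination 3 (1.48) and 23 and 5 without control 2 (1.1). Poly(A) selection removes most organellar RNA, so these values describe what remained.

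Under the combination every tested heat shock protein gene rose above control, as did, with the deposited scaling, 9 of 12 starch and raffinose genes, 10 of 19 of the Calvin cycle and 14 of 27 of oxygen scavenging. HSP17.6A (AT5G12030), a small heat shock protein gene, was at 20.1 ± 31.8 in control and 371100 ± 151000 in the combination, a rise of 15.51 ± 1.39 (adjusted p = 2.99e-06). HSFA2 reached 379100 ± 111000, a rise of 13.72 ± 1.51 (adjusted p = 1.3e-05), and GBSS1 (AT1G32900), the granule-bound starch synthase, rose from 290.2 ± 63.2 to 25520 ± 1960, by 6.47 ± 0.57 (adjusted p = 2.6e-06). GORK (AT5G37500), a potassium channel gene of guard cells, changed by -2.67 ± 0.26 (adjusted p = 4.87e-06). Of 19309 genes, 5750 were higher and 5726 lower than in control. This balance depended on the scaling: higher genes were 50.1% of the calls and 40.9% with upper-quartile scaling (49.8% and 42.9% in heat), and with library totals, tried after the data were seen, 1827 were higher and 12013 lower. List medians that it moved by more than the spread between libraries are also given with it, with the genes then higher and lower. HSP17.6A lay between 14.77 and 16.99 without control 1, 2 or 3. HSFA2 was 14.35 without control 2.

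Among heat shock proteins, 20 of 20 were higher and 0 lower (20 and 0 adjusted over the list alone), median 11.6, camera adjusted p = 1.17e-12 (adjusted p = 0.609, estimated correlation). HSP23.6-MITO rose by 15.35 ± 1.24, HSP17.6II (AT5G12020) by 14.97 ± 1.18, HSP22.0 by 14.87 ± 1.19, HSP21 by 14.81 ± 1.07 and HSP101 by 11.61 ± 1.28. HSP23.6-MITO lay between 14.61 and 16.69, and HSP22.0 between 14.06 and 16.29 without control 1, 2 or 3. HSP17.6II was 14.3 without control 1 and 16.14 without control 2. HSP21 was 15.77 without control 2 and 13.98 without control 3. Among heat shock factors, 10 of 17 were higher and 4 lower (10 and 4 adjusted over the list alone), median 1.12 (library totals 0.169, 8 and 6), camera adjusted p = 0.0448 (adjusted p = 0.633, estimated correlation). The call ended without combination 1 (camera adjusted p = 0.127) or combination 2 (0.0517). HSFA7A (AT3G51910) rose by 9.81 ± 1.09 (10.42 without combination 1), and HSFA7B, at 0 in each control library, was at 14980 ± 9240, at least 6020-fold higher, with the list's median still 1.12 at that bound. Among endoplasmic reticulum chaperones, 12 of 20 were higher and 2 lower (12 and 2 adjusted over the list alone), median 1.46 (library totals 0.508, 9 and 5), camera adjusted p = 0.00676 (adjusted p = 0.633, estimated correlation). ERDJ3A rose by 7.86 ± 0.53, BIP2 by 4.53 ± 0.35 and BIP1 by 3.51 ± 0.34.

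Among starch and raffinose genes, 9 of 12 were higher and 2 lower (9 and 2 adjusted over the list alone), median 1.4 (library totals 0.446, 4 and 2), camera adjusted p = 0.0264 (adjusted p = 0.609, estimated correlation). GOLS1 rose by 8.96 ± 0.6 and the beta-amylase BAM1 (AT3G23920) by 5.05 ± 0.48. Among Calvin cycle genes, 10 of 19 were higher and 0 lower (10 and 0 adjusted over the list alone), median 0.87 (library totals -0.0793, 6 and 7), camera adjusted p = 0.0062 (adjusted p = 0.644, estimated correlation). FBA1 was at 3.02 ± 0.27, the Rubisco activase RCA (AT2G39730) at 2.41 ± 0.38 and RBCS2B at 2.13 ± 0.24. Among flavonoid genes, 12 of 24 were higher and 0 lower (11 and 0 adjusted over the list alone), median 1.23 (library totals 0.28, 9 and 3), camera adjusted p = 0.00559 (adjusted p = 0.633, estimated correlation). CHS rose by 4.67 ± 0.36, CHIL (AT5G05270) by 4.24 ± 0.53 and PAL1 (AT2G37040), the phenylalanine ammonia-lyase, by 3.92 ± 0.56. Among reactive oxygen scavenging enzymes, 14 of 27 were higher and 2 lower (14 and 2 adjusted over the list alone), median 0.65 (library totals -0.299, 4 and 10), camera adjusted p = 0.00975 (adjusted p = 0.633, estimated correlation). APX2 rose by 9.48 ± 0.69 (10.09 without control 3), CAT2 by 4.8 ± 0.52 and the glutathione reductase GR1 (AT3G24170) by 2.98 ± 0.42.

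Among stress zinc finger regulators and NADPH oxidases, 5 of 7 were higher and 1 lower (5 and 1 adjusted over the list alone), median 4.69 (library totals 3.75, 4 and 2), camera adjusted p = 0.0499 (adjusted p = 0.609, estimated correlation). This call ended without control 3 (camera adjusted p = 0.0597), combination 1 (0.0708) or combination 2 (0.0653), with a pseudocount of 0.5 (0.0508), with no filter (0.0827) and with a filter at 50 (0.0787). DREB2A, an AP2-type factor and neither of these, rose by 6.92 ± 0.51, ZAT12 by 6.4 ± 0.62, ZAT6 (AT5G04340) by 4.7 ± 0.55 and ZAT10 by 4.69 ± 0.57 (5.31 without control 2). Among guard cell markers, 0 of 7 were higher and 6 lower (0 and 7 adjusted over the list alone), median -1.49 (library totals -2.44, 0 and 7), camera adjusted p = 0.00638 (adjusted p = 0.609, estimated correlation). KAT1 was at -2.1 ± 0.2 and HT1 (AT1G62400) at -2.02 ± 0.37. Among phloem markers, 0 of 6 were higher and 6 lower (0 and 6 adjusted over the list alone), median -1.29 (library totals -2.24, 0 and 6), camera adjusted p = 0.00851 (adjusted p = 0.609, estimated correlation). The sucrose exporter SWEET12 (AT5G23660) changed by -4.33 ± 0.6 (-5.18 without combination 1), SULTR2;1 by -2.25 ± 0.25 and the sucrose transporter SUC2 (AT1G22710) by -1.62 ± 0.3.

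The largest falls were the terpene synthase TPS03 (AT4G16740) at -6.74 ± 0.65, TAS1A (AT2G27400), a precursor of trans-acting small RNAs, at -6.42 ± 1.1, RK1 (AT1G65790) at -6.28 ± 0.44, MEE14 (AT2G15890) at -6.26 ± 0.49 and BG3 at -6.23 ± 0.74. TPS03 was -7.56 without combination 1. TAS1A lay between -8.36 and -5.46 without combination 1, 2 or 3. MEE14 was -7.02 without combination 1 and -5.59 without combination 2. BG3 was -5.51 without combination 3. ELIP1 rose by 9.49 ± 1.12, ELIP2 by 7.23 ± 1.07, FTSH6 by 7.64 ± 0.49, the clock-related RVE1 (AT5G17300) by 6.35 ± 1.02, CYP707A4 (AT3G19270) by 3.56 ± 0.45, the jasmonate methyltransferase JMT (AT1G19640) by 3.27 ± 0.34, NAP by 3.19 ± 0.45, LHCB4.3 (AT2G40100) by 2.95 ± 0.44, APX1 by 2.44 ± 0.22 and PSB28 by 1.45 ± 0.28. The changes of the jasmonate synthesis genes AOC2 (AT3G25770) and LOX2 were -2.53 ± 0.41 and -2.07 ± 0.43, that of PCNA2 (AT2G29570) -2.23 ± 0.24 and that of CER6 (AT1G68530) -1.34 ± 0.24. ELIP1 was 8.85 without control 1 and 8.87 without combination 2. ELIP2 was 6.55 without combination 2. AOC2 was -3.18 without combination 1. PR1 changed by -4.68 ± 1.36 (adjusted p = 0.00996), and this call ended without control 1 (-3.52, adjusted p = 0.0528). PR1 lay between -6.11 and -3.65 without control 3 or combination 1 or 3.

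LHCB1.1 rose by 1.04 ± 0.38 (adjusted p = 0.0331), NCED3, a gene of abscisic acid synthesis, by 1.24 ± 0.43 (adjusted p = 0.0263), and XCP1 (AT4G35350) by 0.94 ± 0.28 (adjusted p = 0.0126). The LHCB1.1 call ended without control 1, 2 or 3 or combination 1 or 2 (0.88 to 1.12, adjusted p = 0.0524 to 0.109), and with upper-quartile scaling (0.85, adjusted p = 0.0532). That of NCED3 ended without control 2 or 3 or combination 2 (0.92 to 1.27, adjusted p = 0.0532 to 0.114), and with upper-quartile scaling (1.05, adjusted p = 0.0627). That of XCP1 ended without control 2 (0.7, adjusted p = 0.0652) or combination 2 (0.76, adjusted p = 0.057). AG (AT4G18960), the 1 flower marker tested, rose by 1.95 ± 0.48, to 25.8 ± 3.07 normalised counts. With library totals the calls of LHCB1.1, NCED3, AG and PSB28 ended (adjusted p = 0.0586 to 0.812), as did that of XCP1 (-0.01). AOS (0.09 ± 0.24, adjusted p = 0.765) and JAZ10 (0.75 ± 0.58, 0.28) did not pass. In the lists without a camera call (adjusted p 0.0572 to 0.997), the members higher and lower (in brackets adjusted over the list alone) were 3 and 5 of 15 jasmonate synthesis genes, 6 and 4 of 20 jasmonate signalling genes, 10 and 5 of 24 abscisic acid genes, 2 and 7 of 12 salicylic acid genes (2 and 9), 7 and 0 of 20 antenna genes (4 and 0), 10 and 0 of 24 photosystem subunit genes, 7 and 3 of 21 photosystem II repair genes, 5 and 1 of 6 early light-induced genes, 9 and 9 of 19 clock genes, 1 and 2 of 16 cell cycle genes, 2 and 2 of 8 senescence genes, 0 and 1 of 6 epidermis markers and 1 and 0 of 5 xylem markers. The photosystem subunit list was called without control 1 (camera adjusted p = 0.0312), control 3 (0.0467) or combination 3 (0.0401), and that of salicylic acid without control 3 (0.0341) or combination 2 (0.0429) and with no filter (0.0316). In a fit of only the 2 groups, photosystem subunits (0.0153), antenna (0.00957) and early light-induced genes (0.0414) were called.

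Adding heat to high light raised every tested heat shock protein gene and most antenna genes and lowered most flavonoid genes. HSP21 stood at 4.13 ± 7.16 in high light and 97660 ± 44800 in the combination, 15.24 ± 1.07 (adjusted p = 1.24e-06), and LHCB1.1 at 14500 ± 4330 and 325600 ± 66400, 4.51 ± 0.38 (adjusted p = 3.35e-06). UF3GT (AT5G54060), an anthocyanin glycosyltransferase, stood at 3680 ± 1020 and 10.4 ± 1.86, -8.31 ± 0.72 (adjusted p = 3.72e-06). Of 19309 genes, 5421 were higher and 5654 lower in the combination than in high light (1962 and 11755 with library totals). HSP22.0, HSP17.6A, HSP23.6-MITO and HSP17.4 rose by 14.98, 13.83, 13.48 and 13.4, HSP101 by 9.82 ± 1.28, HSFA2 by 8.6 ± 1.51 and APX2 by 8.4 ± 0.69. TT7 changed by -8.31 ± 0.49, VSP1 by -8.08 ± 1.09, PAP2 by -7.87 ± 0.8, the anthocyanin malonyltransferase AT5MAT (AT3G29590) by -7.8 ± 0.7, CHS by -2.99 ± 0.36 and LOX2 by -2.57 ± 0.43. NCED3, ZAT10 and ZAT12 rose by 2.13, 3.47 and 2.98. APX1 (0.13, adjusted p = 0.633), ELIP1 (-0.81, 0.552), AOS (-0.12, 0.682) and JAZ10 (0.52, 0.464) did not pass. ELIP2 changed by -3.02 ± 1.07 (adjusted p = 0.0277), and this call ended without high light 1 or 3 or combination 1 or 3 (-2.49 to -2.77, adjusted p = 0.0739 to 0.103), with -3.81 without high light 2. HSP21 lay between 14.61 and 16.48, and HSP17.4 between 12.06 and 14.1 without high light 1, 2 or 3. Without high light 1 and 3 in turn, HSP22.0 was 13.93 and 16.26, HSP17.6A 12.69 and 15.13, HSP101 8.87 and 10.71, and HSFA2 7.16 and 9.76. HSP23.6-MITO was 12.15 without high light 1 and 14.3 without high light 2. APX2 was 9.01 without high light 3. TT7 was -8.93 and ZAT12 2.38 without high light 2. VSP1 was -8.79 without high light 2 and -8.95 without combination 1. PAP2 was -8.85 without combination 1 and -7.02 without combination 2.

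Among antenna proteins, 18 of 20 were higher and 0 lower (18 and 0 adjusted over the list alone), median 2.71 (library totals 1.81, 16 and 1), camera adjusted p = 1.34e-08 (adjusted p = 0.609, estimated correlation). Among photosystem subunits, 22 of 24 were higher and 1 lower (22 and 1 adjusted over the list alone), median 1.75 (library totals 0.852, 19 and 2), camera adjusted p = 8.07e-09 (adjusted p = 0.633, estimated correlation). Among flavonoid genes, 1 of 24 were higher and 21 lower (1 and 22 adjusted over the list alone), median -3.81 (library totals -4.68, 1 and 23), camera adjusted p = 2.55e-08 (adjusted p = 0.609, estimated correlation). Among heat shock proteins, 20 of 20 were higher and 0 lower (20 and 0 adjusted over the list alone), median 9.76, camera adjusted p = 2.92e-12 (adjusted p = 0.609, estimated correlation). Among heat shock factors, 9 of 17 were higher and 1 lower (9 and 1 adjusted over the list alone), median 1.23 (library totals 0.339, 8 and 7), camera adjusted p = 0.0158 (adjusted p = 0.609, estimated correlation). Among endoplasmic reticulum chaperones, 13 of 20 were higher and 1 lower (13 and 1 adjusted over the list alone), median 1.3 (library totals 0.405, 9 and 6), camera adjusted p = 0.00374 (adjusted p = 0.633, estimated correlation). The heat shock factor call ended without combination 1 (camera adjusted p = 0.0642). Among guard cell markers, 0 of 7 were higher and 6 lower (0 and 6 adjusted over the list alone), median -1.47 (library totals -2.33, 0 and 7), camera adjusted p = 0.00695 (adjusted p = 0.609, estimated correlation). Among phloem markers, 0 of 6 were higher and 6 lower (0 and 6 adjusted over the list alone), median -0.95 (library totals -1.85, 0 and 6), camera adjusted p = 0.0192 (adjusted p = 0.609, estimated correlation), and 0.0624 with library totals. Among photosystem II repair genes, 9 of 21 were higher and 0 lower (9 and 0 adjusted over the list alone), median 0.46 (library totals -0.439, 4 and 10), camera adjusted p = 0.0413 (adjusted p = 0.771, estimated correlation). The call ended with library totals (0.321), TMM (0.0599) or upper-quartile scaling (0.0653) and without high light 3 (0.0614) or combination 1 (0.0708). Among starch and raffinose genes, 7 of 12 were higher and 3 lower (7 and 3 adjusted over the list alone), median 1.75 (library totals 0.85, 6 and 4), camera adjusted p = 0.0499 (adjusted p = 0.609, estimated correlation). The call ended without high light 2 (0.0515), high light 3 (0.0518), combination 1 (0.0571) or combination 2 (0.0630), with a pseudocount of 0.5 (0.0506) and with a filter at 50 (0.0566).

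With deposited scaling, adding high light to heat raised 17 of 20 heat shock protein, 20 of 24 photosystem and 13 of 20 antenna genes. HSFA7B stood at 286 ± 346 in heat and 14980 ± 9240 in the combination, 7.74 ± 1.57 (adjusted p = 0.00134), and HSP70B (AT1G16030) at 133200 ± 198000 and 1185000 ± 454000, 5.82 ± 1.58 (adjusted p = 0.00775), though edgeR gave 3.09 (adjusted p = 0.0592) for HSP70B. TAS1A stood at 507 ± 82 in heat and changed by -7.04 ± 1.1 (adjusted p = 0.000264), with 54.6 in combination 1 and 0 in the other libraries of that group. Of 19309 genes, 5388 were higher and 5219 lower in the combination than in heat (1577 and 11094 with library totals). ELIP1 rose by 5.85 ± 1.12, PUM21 (AT5G09610), a Pumilio RNA-binding protein gene, by 5.73 ± 0.92, HSFA2 by 5.66 ± 1.51, HSP101 by 5.02 ± 1.28 and ELIP2 by 4.56 ± 1.07. ZAT12, ZAT10, CHS and LHCB1.1 rose by 3.78, 2.66, 2.18 and 1.72. The microRNA precursor MIR167d (AT1G31173) changed by -5.58 ± 0.79, VSP2 by -5.34 ± 1.11, TAS1B (AT1G50055) by -5.23 ± 0.72, VSP1 by -5.02 ± 1.09 and LOX2 by -1.64 ± 0.43. AOS (0.44, adjusted p = 0.132), JAZ10 (1.07, 0.133) and NCED3 (0.58, 0.275) did not pass, though without heat 1 AOS (0.68) and NCED3 (1.18) did. APX1 rose by 0.71 ± 0.22 (adjusted p = 0.0171) and APX2 by 2.01 ± 0.69 (adjusted p = 0.0251), and the APX1 call ended without heat 1 (0.51, adjusted p = 0.0535) or combination 2 (0.57, adjusted p = 0.0753) and that of APX2 without heat 1 (1.44, adjusted p = 0.107) or combination 2 (1.47, adjusted p = 0.115), and both with library totals (-0.16 and 1.15). Without heat 1 and combination 2 together, the HSFA2 call ended as well (3.6, adjusted p = 0.0625). HSFA7B lay between 5.16 and 9.49 without heat 1, 2 or 3 or combination 1. Without heat 1 and 3 in turn, HSP70B was 3.25 and 7.91, HSFA2 3.76 and 7.38, and HSP101 3.25 and 6.57. TAS1A lay between -8.98 and -6.08 without combination 1, 2 or 3. ELIP1 lay between 4.12 and 6.74, and ELIP2 between 3.09 and 5.32 without heat 1, 2 or 3 or combination 2. PUM21 lay between 4.64 and 6.69 without heat 1 or 3 or combination 2. ZAT12 was 3.04 and LOX2 -1.03 without heat 1. MIR167d lay between -6.3 and -4.58 without heat 1 or combination 1 or 2. VSP2 lay between -6.7 and -4.66 without heat 1 or 2 or combination 1, 2 or 3. TAS1B was -6.26 without combination 1 and -4.19 without combination 2. VSP1 lay between -6.06 and -4.17 without heat 1 or 2 or combination 1.

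Among photosystem subunits, 20 of 24 were higher and 0 lower (21 and 0 adjusted over the list alone), median 1.08 (library totals 0.211, 6 and 1), camera adjusted p = 2.07e-06 (adjusted p = 0.633, estimated correlation). Among heat shock proteins, 17 of 20 were higher and 0 lower (18 and 0 adjusted over the list alone). The median was 3.38 (library totals 2.51, 14 and 0), camera adjusted p = 6.72e-05 (0.633, estimated correlation). Among antenna proteins, 13 of 20 were higher and 0 lower (14 and 0 adjusted over the list alone), median 0.94 (library totals 0.0716, 7 and 1), camera adjusted p = 0.00106 (adjusted p = 0.682, estimated correlation). Among Calvin cycle genes, 12 of 19 were higher and 0 lower (13 and 0 adjusted over the list alone), median 0.92 (library totals 0.045, 5 and 5), camera adjusted p = 0.000935 (adjusted p = 0.633, estimated correlation). Among flavonoid genes, 15 of 24 were higher and 2 lower (16 and 2 adjusted over the list alone), median 2.09 (library totals 1.23, 11 and 4), camera adjusted p = 0.00169 (adjusted p = 0.633, estimated correlation). Among cell cycle genes, 12 of 16 were higher and 2 lower (13 and 2 adjusted over the list alone), median 1.54 (library totals 0.671, 8 and 2), camera adjusted p = 0.00152 (adjusted p = 0.633, estimated correlation). Among photosystem II repair genes, 11 of 21 were higher and 0 lower (11 and 0 adjusted over the list alone), median 0.49 (library totals -0.376, 2 and 7), camera adjusted p = 0.0103 (adjusted p = 0.644, estimated correlation). Among starch and raffinose genes, 7 of 12 were higher and 1 lower (7 and 1 adjusted over the list alone), median 1.63 (library totals 0.76, 7 and 2), camera adjusted p = 0.0176 (adjusted p = 0.609, estimated correlation). Among phloem markers, 0 of 6 were higher and 6 lower (0 and 6 adjusted over the list alone), median -1.11 (library totals -1.98, 0 and 6), camera adjusted p = 0.00488 (adjusted p = 0.609, estimated correlation). With library totals the photosystem II repair call ended (camera adjusted p = 0.275). Of 79 chloroplast genome genes, 13 were higher and 13 lower (median 0.55), against 5 and 21 without combination 2 (median -0.333) and 23 and 11 without combination 3 (0.984).

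The interaction asks whether the effect of high light differed with and without heat, as (combination - heat) - (high light - control). Most antenna genes had a positive interaction (18 of 20): for LHCB1.1 the effects without and with heat were -3.48 and 1.72, an interaction of 5.2 ± 0.54 (adjusted p = 3.07e-05). For CHS the effects were 7.66 and 2.18, an interaction of -5.48 ± 0.51 (adjusted p = 1.7e-05). Of 19309 genes, 4443 had a positive and 4484 a negative interaction (1812 and 8803 with library totals). The largest positive values were PORA at 10.3 ± 0.99, LHCB2.3 at 9.38 ± 1.11, the asparagine synthetase ASN1 (AT3G47340) at 8.75 ± 0.81, LHCB1.4 at 8.72 ± 0.71 and PGL1 at 8.05 ± 0.63. The largest negative ones were the beta-amylase BAM5 (AT4G15210) at -11.5 ± 1.35, CSLA01 (AT4G16590) at -11.21 ± 1.51, VSP1 at -10.1 ± 1.54, VSP2 at -9.24 ± 1.57 and TT7 at -8.73 ± 0.69. Without heat 1 and 3 in turn, PORA was 9.3 and 11.22, and LHCB2.3 8.61 and 10.61. ASN1 was 9.49 without heat 3. BAM5 was -10.54 without control 2 and -12.94 without control 3. CSLA01 lay between -12.12 and -9.6 without heat 1, 2 or 3 or combination 1. VSP1 lay between -11.14 and -9.11 without control 2 or 3, high light 2, heat 1 or 2 or combination 1. VSP2 lay between -10.6 and -8.47 without control 2 or 3, heat 1 or 2 or combination 1, 2 or 3. TT7 was -9.35 without high light 2.

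Among antenna proteins, 18 of 20 were higher and 1 lower (18 and 1 adjusted over the list alone), median 3.43 (library totals 2.61, 17 and 2), camera adjusted p = 5.22e-09 (adjusted p = 0.609, estimated correlation). LHCB2.2 (AT2G05070) was at 5.28 ± 0.6. Among photosystem subunits, 23 of 24 were higher and 1 lower (23 and 1 adjusted over the list alone), median 2.14 (library totals 1.33, 22 and 1), camera adjusted p = 3.26e-11 (adjusted p = 0.609, estimated correlation). PSAD2 was at 3.94 ± 0.48, PSAN at 3.6 ± 0.37 and PSAO at 3.57 ± 0.35. Among photosystem II repair genes, 10 of 21 were higher and 1 lower (11 and 1 adjusted over the list alone), median 0.64 (library totals -0.177, 4 and 5), camera adjusted p = 0.00922 (adjusted p = 0.644, estimated correlation), and 0.0947 with library totals, with LQY1 (AT1G75690), HHL1 (AT1G67700) and TLP18.3 (AT1G54780) at 3.3, 2.18 and 1.85. Among flavonoid genes, 1 of 24 were higher and 19 lower (1 and 21 adjusted over the list alone), median -3.5 (library totals -4.3, 1 and 22), camera adjusted p = 8.47e-08 (adjusted p = 0.609, estimated correlation). The regulator MYB111 (AT5G49330) was at -7.27 ± 0.54 and PAP2 at -7.09 ± 1.14, and PAP2 was -8.07 without combination 1, -6.24 without combination 2 and -6.35 (adjusted p = 0.0738) in edgeR. Among salicylic acid genes, 7 of 12 were higher and 0 lower (7 and 0 adjusted over the list alone), median 2.28 (library totals 1.61, 6 and 1), camera adjusted p = 0.00608 (adjusted p = 0.609, estimated correlation). SARD1 was at 5.18 ± 0.77 (5.86 without combination 1), PBS3 (AT5G13320) at 4.52 ± 0.86 (3.79 without heat 2 and 5.38 without heat 3) and WRKY70 at 4.49 ± 0.47. Among cell cycle genes, 11 of 16 were higher and 2 lower (12 and 2 adjusted over the list alone), median 1.68 (library totals 0.864, 6 and 2), camera adjusted p = 0.00303 (adjusted p = 0.633, estimated correlation). CYCB1;2 was at 3.33 ± 0.96 (4.15 without heat 1 and 2.39 without heat 2), MCM7 (AT4G02060) at 2.97 ± 0.31 and PCNA1 (AT1G07370) at 2.5 ± 0.37.

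**Figure D3:**
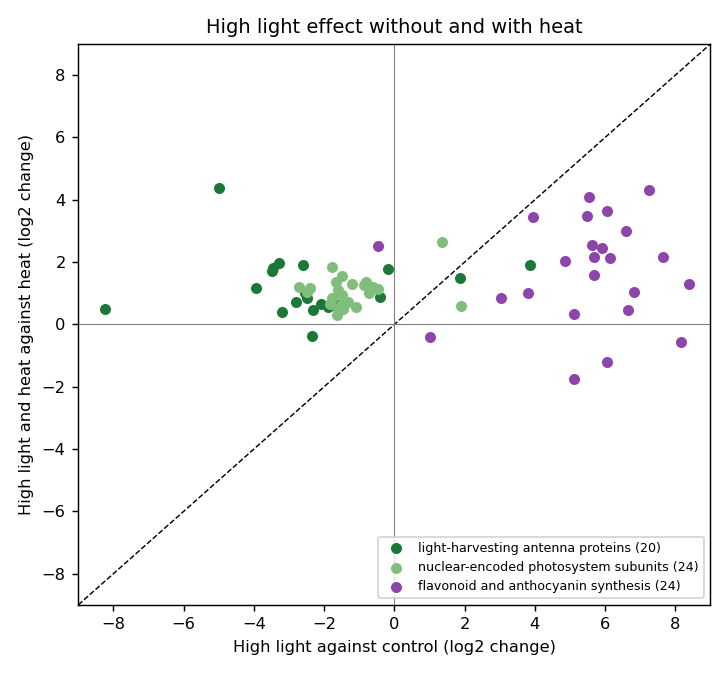
Log2 change of high light against control (x axis) and of the combination against heat (y axis) for each tested member of 3 gene lists; the dashed line marks equal effects. Most antenna and photosystem genes lie left of 0 and above 0 (median interactions 3.43 and 2.14), and most flavonoid genes lie below the line (median interaction -3.5).

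Among heat shock proteins, 7 of 20 were higher and 0 lower (4 and 0 adjusted over the list alone). The median was 1.83 (library totals 0.957, 3 and 0), camera adjusted p = 0.0272 (0.911, estimated correlation). Fry lost this call alone (adjusted p = 0.238). HSP70B was at 5.97 ± 2.24 (adjusted p = 0.0439), BAG6 (AT2G46240) at 4.67 ± 1.54 (adjusted p = 0.0256) and HSP70T-2 (AT2G32120) at 3.24 ± 1.01. The list's call ended without control 2 (camera adjusted p = 0.0769), high light 1 (0.112), heat 1 (0.102) or combination 2 (0.0602). The HSP70B call ended with any library but heat 1 or 3 left out (5.62 to 6.46, adjusted p = 0.0518 to 0.0867). The BAG6 call ended without control 3, high light 1 or 2 or combination 2 or 3 (4.27 to 4.61, adjusted p = 0.0501 to 0.06). EdgeR gave 3.19 (adjusted p = 0.153) for HSP70B and 3.22 (adjusted p = 0.0784) for BAG6. Without heat 1 and 3 in turn, HSP70B was 3.4 and 8.06, and HSP70T-2 2.12 and 4.01. BAG6 lay between 3.12 and 6.1 without heat 1 or 3 or combination 1. HSFA7B passed (adjusted p = 0.0326) but lay at 0 in control and near 0 in high light, so no change is given, and its call ended without control 1, 2 or 3, high light 1 or 2 or combination 2 or 3 (adjusted p = 0.0563 to 0.0724) and in edgeR (adjusted p = 0.926). Among phloem markers, 0 of 6 were higher and 4 lower (0 and 5 adjusted over the list alone), median -0.95 (library totals -1.77, 0 and 6), camera adjusted p = 0.0445 (adjusted p = 0.609, estimated correlation). SWEET12 was at -3.83 ± 0.84 (-4.68 without combination 1), SULTR2;1 at -1.56 ± 0.35 and AHA3 (AT5G57350) at -1.07 ± 0.24. That call ended without control 2 (0.0640), high light 2 (0.0521), heat 1 (0.0706), heat 2 (0.0565) or combination 2 (0.0574), with a filter at 50 (0.054) and with library totals (0.0721).

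The largest interaction in each remaining list was SEN1 at 7.72 ± 0.62, BIP3 (AT1G09080) at 6.02 ± 1.49, ZAT7 (AT3G46090) at 5.86 ± 1.04, RVE1 at 5.77 ± 1.45, GOLS2 at 5.27 ± 0.49, CYP707A2 at -4.71 ± 0.6, FSD1 (AT4G25100) at -3.14 ± 0.75, AOC2 at -2.78 ± 0.58, KAT1 at -2.59 ± 0.28, GAPA-2 (AT1G12900) at 1.5 ± 0.29, XCP2 at -1.33 ± 0.37 and CER5 at 1.03 ± 0.26. With library totals the GAPA-2 and CER5 calls ended (adjusted p = 0.0571 and 0.58). BIP3 lay between 4.98 and 7.4 without control 3 or heat 1 or 3. ZAT7 was 6.49 without control 3 and 5.1 without heat 1. RVE1 was 4.6 without heat 1 and 7.42 without heat 3. CYP707A2 was -5.33 and AOC2 -3.43 without combination 1. FSD1 was -3.8 without combination 3. EdgeR gave 4.15 (adjusted p = 0.0604) for RVE1. ELIP2 was at -5.69 ± 1.51, LOX2 at -2.14 ± 0.61 and APX1 at -1.59 ± 0.32. ELIP2 lay between -7.16 and -4.93 without high light 2, heat 1, 2 or 3 or combination 2. LOX2 was -1.53 without heat 1. ELIP1 was at -4.45 ± 1.58 (adjusted p = 0.0357), a call that ended without control 1 or 3, high light 1 or 3, heat 2 or 3 or combination 1 or 3 (-3.55 to -4.66, adjusted p = 0.0513 to 0.0925), and was -6.18 without heat 1. HSP101 (3.23, adjusted p = 0.16), HSFA2 (0.53, 0.854), APX2 (0.93, 0.452), AOS (0.23, 0.594), JAZ10 (0.84, 0.421), NCED3 (1.47, 0.0672), ZAT10 (1.44, 0.159) and ZAT12 (0.37, 0.753) did not pass, though NCED3 did without heat 1 (2.07) and HSP101 without heat 3 (4.78). In the lists without a camera call (adjusted p 0.134 to 0.924), the members higher and lower (in brackets adjusted over the list alone) were 2 and 1 of 17 heat shock factors (1 and 0), 3 and 4 of 20 endoplasmic reticulum chaperones, 3 and 4 of 15 jasmonate synthesis genes, 4 and 3 of 20 jasmonate signalling genes, 3 and 3 of 24 abscisic acid genes, 2 and 2 of 6 early light-induced genes, 5 and 1 of 19 Calvin cycle genes (4 and 1) and 3 and 7 of 27 oxygen scavenging genes. They were 1 and 1 of 7 stress zinc finger and NADPH oxidase genes, 7 and 6 of 19 clock genes, 7 and 2 of 12 starch and raffinose genes, 4 and 1 of 8 senescence genes, 0 and 3 of 7 guard cell markers, 1 and 0 of 6 epidermis markers and 0 and 1 of 5 xylem markers, and AG did not pass.

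In the combination 2266 genes were higher and 2525 lower than in each of the other 3 groups. By the smallest of 3 changes, the leading higher genes were HSFA7B, HSP70B, PUM21, HSFA2 and HSFA7A, at 14980 ± 9240, 1185000 ± 454000, 2451 ± 2300, 379100 ± 111000 and 22000 ± 12400 in the combination and 286, 133200, 58.9, 29470 and 1124 on average in heat, the next highest group. HSFA2 did not pass against heat without heat 1 and combination 2. The leading lower genes were TAS1A, TAS1B, PRR3 (AT5G60100), GRP7 (AT2G21660) and TAS1C (AT2G39675). PRR3, a clock gene, stood at 2606 ± 372 in control, 2927 ± 321 in high light, 1946 ± 645 in heat and 119 ± 143 in the combination. GRP7, a clock-regulated RNA-binding protein gene, stood at 152700 ± 25800, 148200 ± 16500, 175700 ± 67300 and 12190 ± 16400, with 31159, 2832 and 2572 in the 3 combination libraries. TAS1B stood at 205 ± 7.7 in control and 6.63 ± 8.74 in the combination, and TAS1C at 280.2 ± 22.9 and 14.5 ± 19. In each of these 5 lower genes combination 1 was the highest library of its group.

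The 3 comparisons with control share the control libraries, which by themselves correlate their changes. Heat and the combination shared 2830 higher and 2629 lower genes, with 658 in opposite directions, where independent lists would share 1413, 1418 and 2831. High light and heat shared 1589 higher and 1728 lower genes with 555 opposite (859, 794 and 1654 for independent lists), and high light and the combination 1918 and 1703 with 693 opposite (1041, 950 and 1991). The correlation of changes across genes was 0.677 for heat and the combination, 0.441 for high light and heat and 0.384 for high light and the combination, where simulated unchanged groups gave 0.475, 0.501 and 0.476 in 100 simulations. The covariances were 1.48, 0.615 and 0.672, and the simulated ones 0.057, 0.0571 and 0.057. Genes higher in all 3 comparisons numbered 1085 and genes lower in all 3 numbered 1199.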

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

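The tests of explanations for the 3 patterns below were chosen only after the results were seen; the interaction test and the counts of other splits were not. The effect of high light differed with and without heat by the interaction test for 4443 genes in the positive and 4484 in the negative direction. Among the genes given always, the difference passed for APX1 (-1.59), ELIP1 (-4.45), ELIP2 (-5.69), LOX2 (-2.14), CHS (-5.48) and LHCB1.1 (5.2). Of 100 drawn splits of the 12 libraries into 4 groups of 3, 1, the real one, called as many as 8927 genes, and the highest other called 14, but the others hold the effects of heat and light as spread (median residual SD 0.628 against 0.308), so this does not decide whether chance can be excluded. For the 5 other comparisons 1 of the 10 splits of 6 libraries, the real one, called as many genes, and 10 splits are too few for a share under 0.05. The real counts were 6701 in high light, 9528 in heat and 11476 in the combination, with 11075 against high light and 10607 against heat. The highest other counts were 0, 0, 0, 0 and 174.

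Without heat, high light lowered 37 of 44 antenna and photosystem genes and raised 4; with heat 33 were higher and 0 lower, and both lists lost their calls with an estimated correlation (adjusted p = 0.609 and 0.633 without heat, 0.682 and 0.633 with it). Over 5 scalings the lowest median interaction was 1.66 (lower quartile 1.14) and the highest median change without heat -1.65 (upper quartile -1.04), which argues against scaling as the cause of these, but the rise on top of heat cannot be told apart from scaling, since with library totals its median was 0.159 (quartiles -0.237 and 0.534). With library totals without reads of the 20 matched heat shock proteins (28 listed), the median interaction was 1.89 (lower quartile 1.37). This argues against those reads as the cause. The 15 members without a near-identical copy had a median interaction of 2.61 (1.67 to 3.6, 15 called higher), which argues against reads shared between copies. A biological difference in how strongly high light lowered these genes may lie behind the interaction, as a hypothesis found and tested on the same data.

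The 3 heat libraries differed in heat shock protein levels, with a median ratio of 11.2 between the highest and lowest library. Their read totals differed by a ratio of 1.06, which argues against it as the cause, and 100% of the 20 tested members lay above every control library in each heat library, which argues against a control sample labelled as heat. RNA of the combination mixed into heat library 3 stays open: its heat shock proteins lay at a median 23.8% of their combination level, and light-raised genes at 54.9% (512 genes, with 29.6% in control) and at 25.8% over the 83 of them with low control levels, a set chosen after the first value was seen. In heat libraries 1 and 2 the 83 genes lay at 4.99% and 11.2% and the heat shock proteins at 2.52% and 11.4%. No biological explanation was tested, and calls against heat could carry this.

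All 39 tested mitochondrial genome genes were higher in heat than in control (median 4.42). The chloroplast median was 0.534, below the mitochondrial lower quartile of 3.73. This cannot decide on less complete poly(A) selection, as equal action on both genomes was not tested. The lowest heat library had 5.6 times the share of reads of the highest control library, which argues against scaling. An effect of heat on these transcripts may remain, as a hypothesis.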

How the results depend on the processing

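The tests without heat library 1 and combination library 2 together, on all listed loci, on nuclear genes, on lists without CNX2 and MET1 and with library totals were chosen only after the result was seen. Counts of genes stayed within 1.5 times under other pseudocounts and filters, TMM, upper-quartile scaling, the robust estimate, edgeR, DESeq2, the replicate block and each library left out. EdgeR shared 94.6% to 98.7% of the calls, with 0 in the opposite direction. Only the 2 groups compared gave 5134 lower genes in high light. With an absolute log2 change of at least 1 there were 2052 and 1848 higher and lower genes in high light, 2702 and 2919 in heat, 3394 were higher in the combination, 3361 and 3719 differed from high light, 3161 and 3221 from heat, and 1114 and 1468 stood apart. Shared genes then numbered 757 and 943 for high light and heat, 859 and 947 for high light and the combination and 1548 and 1597 for heat and the combination. With an adjusted p under 0.01, 2000 were lower in high light, 2837 and 2888 passed in the interaction and 1404 and 1637 stood apart. These stricter limits pass fewer genes by construction. With an estimated correlation 0 of the 49 list calls passed.

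Leaving out each library in turn gave 2697 to 2923 higher and 2303 to 2573 lower genes in high light, 3784 to 5144 and 3816 to 4999 in heat, 5023 to 5604 and 4930 to 5713 in the combination, 3691 to 4832 and 3748 to 5141 in the interaction, and 44 to 53 list calls. Without heat library 1 and combination library 2, heat had 5271 higher and 5177 lower genes, the combination 5536 and 5577, the interaction 4105 and 4143, and 1692 and 1926 stood apart. Same-number residuals correlated over 0.1 in every pair of control and high light (0.16, 0.16 and 0.31) and of high light and heat (0.15 each), but in 1 of the 12 other pairs (-0.076 to 0.11), so whether the numbers pair libraries stays open. The replicate block gave 3378 and 3114 genes in high light and 52 list calls, newly heat shock proteins in high light (0.0184), salicylic acid in the combination (0.0444) and early light-induced proteins against heat (0.0485), and CER5 in high light did not pass (-0.54, adjusted p = 0.0565).

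Library totals aside, camera called more lists against heat under some settings: early light-induced proteins (lowest adjusted p = 0.0176), guard cell markers (0.0202) and oxygen scavenging (0.0317). Calls near the threshold also ended with no filter for ERDJ3A, SULTR2;1 and CER5 in high light, LHCB1.1 in the combination and the interaction of HSP70B (adjusted p = 0.0527 to 0.0588), with a pseudocount of 10 for ERDJ3A (0.0536), with a pseudocount of 0.5 (0.0578) and in DESeq2 (0.553) for the interaction of HSFA7B, and with the robust estimate for the interactions of HSP70B (0.07) and ELIP1 (0.0585). In fits of only the 2 groups they ended for the Calvin cycle list in high light, LHCB2.3 and ELIP1 in heat and APX1 against heat (0.0519 to 0.102). Without heat library 1 and combination library 2 they ended for HSFA2, APX1 and APX2 against heat, LHCB2.3 and ATML1 in heat and the interaction of BAG6 (0.0604 to 0.32), and for the lists of heat shock proteins (0.177) and phloem (0.0931) in the interaction, stress zinc fingers in the combination (0.0616) and starch against high light (0.0582).

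Library totals moved the median of all genes by -0.95 in the combination, -0.897 against high light, -0.867 against heat and -0.815 in the interaction. Higher and lower genes then numbered 1827 and 12013, 1962 and 11755, 1577 and 11094, and 1812 and 8803, and 547 and 7659 stood apart. List medians changed sign for the Calvin cycle (-0.0793) and oxygen scavenging (-0.299, or -0.00739 without heat shock protein reads) in the combination and for photosystem II repair against high light (-0.439 and -0.148), against heat (-0.376 and -0.153) and in the interaction (-0.177). Calls ended with a change of sign for XCP1 in the combination (-0.01) and APX1 against heat (-0.16), without one for 9 other values (adjusted p = 0.0571 to 0.812) and for 5 lists (0.0624 to 0.321), and lists not called before passed at 0.000723 to 0.0478. Of values that had not passed, AOS was -0.86 in the combination (adjusted p = 0.0174), -1.02 against high light (0.00702), -0.43 against heat and -0.59 in the interaction, JAZ10 -0.19 in the combination and -0.37 against high light, APX1 -0.77 against high light (adjusted p = 0.000902), NCED3 -0.29 against heat and the interactions of HSFA2 and ZAT12 -0.29 and -0.46.

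The values that changed sign under other settings had not passed the test, and here and above the cause was not tested. AOS in the combination was -0.03 with TMM, -0.1 with upper-quartile scaling and -0.01 in edgeR, and APX1 in the combination against high light was -0.04 with upper-quartile scaling. The interaction of HSFA2 was -2.35 in edgeR and -2.31 in DESeq2, and that of ZAT12 -0.19 and -0.16. Without heat library 1 and combination library 2, APX1 against high light was -0.01 and AOS 0, and the interactions of HSFA2, APX2 and ZAT12 were -1.53, -0.19 and -0.63. Leaving out 1 library gave JAZ10 -0.11 to 0.71 in high light and -0.68 to 0.37 in heat, AOS -0.04 to 0.28 in the combination and -0.21 to 0 against high light, APX1 -0.01 to 0.24 against high light, and interactions of -1.37 to 2.25 for HSFA2 and -0.38 to 0.94 for ZAT12.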

Other observations

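All tests in this part were chosen after the data were seen, with families defined by words in the product names of the reference. Of 224 tests of 16 families over 19150 genes with a product name (Fisher's exact test, two-sided, Benjamini-Hochberg), 81 passed. Ribosomal protein genes were higher in high light for 243 of 310 members (78.4% against 17.2% of other genes, median 1.02, adjusted p = 1.34e-117) and in the combination for 219 (adjusted p = 6.57e-49), and in heat 58 were higher and 60 lower. Genes of pentatricopeptide repeat proteins, which bind organellar RNA, were higher in high light for 82 of 275 (median 0.709, adjusted p = 1.57e-05), lower in the combination than in high light for 195 (median -1.45, adjusted p = 1.46e-44), had a negative interaction for 174 (adjusted p = 2.09e-44) and were lower than in all 3 other groups for 111 (adjusted p = 2.42e-28). Members of a family move together, so these p-values overstate the evidence. Library totals moved the median of all genes in the combination by -0.95, more than the ribosomal (0.769) and proteasome medians there.

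Proteasome subunit genes were higher in the combination for 34 of 42 (median 0.796, adjusted p = 8.15e-11) and in heat for 16 (adjusted p = 0.108). Histone genes were lower in heat for 39 of 48 (median -1.72, adjusted p = 5.45e-15) and had a positive interaction for 33 (adjusted p = 2.2e-10). Receptor-like kinase genes were lower in the combination for 78 of 101 (median -1.65, adjusted p = 1.68e-21).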
